A study of Homo sapiens with 3 samples.

How the data were processed

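Total RNA from 3 stable lines of PANC-1, an established human pancreatic ductal adenocarcinoma cell line, was labelled with biotin and hybridised to Affymetrix 3' expression arrays, 1 array per line. Per the labels, the control line carried the empty retroviral MSCV vector, and the others expressed wild-type JMJD3 or a mutant JMJD3. The labels do not say which mutation it is, whether each line is a clone or a pool, or how cultures were timed. There were no replicates, so no difference below has a replicate check, no test was run and no p-value is given. The number of arrays limits the precision of every value.

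The deposited values were on a log2 scale, from 2.42 to 14.94 over 54613 probe sets and written to 2 decimals. The submitters' processing notes name MAS5, the Affymetrix signal algorithm, with no settings. The deposited log2 columns had nearly the same distribution, with a largest gap of 0.14 between the sorted columns, and 21.0% of the probe sets held the same value in all 3 arrays. The normalization between arrays is not given in the sources used here, and a difference of 0 therefore does not show that 2 transcript levels were equal.

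Probe sets were named through the platform annotation. Of the 54613 probe sets, 41091 had 1 gene symbol, 1801 had several and were given no name, and 11721 were not listed and are unnamed here. The gene identifiers of 41037 of the 41091 matched the RefSeq gene table of assembly GRCh38.p14, and 0 symbols had to be updated. No genome build comes with the array values, so that table served only for names and no coordinates are printed. The probe set with the highest mean log2 signal over the 3 arrays stood for its gene, which left 19775 genes, 10523 of them with several probe sets. Probe sets whose identifier ends in _s_at or _x_at have probes shared with other transcripts, so a value from one can include related genes.

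Signals were floored at the pooled median of all arrays (log2 5.48), as no detection calls were used. A gene was measured in a comparison where at least 1 of the 2 arrays was over the floor. A difference is the log2 signal of one array minus that of another after flooring, and a fold is 2 raised to it. Where one side lay at or under the floor the fold is a lower bound, written as at least N-fold, and where both did none is given. Genes were counted as higher or lower from a 2-fold difference. Bright genes were those over the pooled 75th percentile (log2 7.59).

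The 3 comparisons were wild-type JMJD3 against control, mutant JMJD3 against control, and wild-type against mutant. For 31 gene lists the median difference over measured members was set against 10000 random lists of the same size, matched on 10 classes of mean signal. The percentile describes these arrays and is no p-value. Since both JMJD3 arrays share the control, the correlation and overlap of their differences were set against 1000 shuffles of each gene's 3 values among the arrays, and overlaps also against independent lists.

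The samples' groups, gene lists, comparisons, 7 alternatives and the rule for named genes were fixed before the data were examined. The rule names KDM6B, HKDC1 and the spectrin genes. In each comparison it adds the 10 genes with the largest difference on each side that were over the floor in both arrays, bright in at least 1 and of one direction in all measured probe sets. It adds the 5 brightest genes on each side with the other array at the floor, and the 10 on each side by which the wild-type array stood most apart from both others. From each list described it takes up to 4 members with the largest difference. Uncharacterised loci and non-coding transcripts that it selects are mostly left out of the text. The alternatives were scaling the arrays to one median, quantile normalization, floors at the 40th and 60th percentile, no floor but an offset of the pooled median signal, the median over a gene's probe sets, and leaving out shared probe sets.

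The gene-level step was tested on simulated data in which 200 genes were changed in the wild-type array against control. All 50 genes given a log2 change of 1.5 and all 50 given -1.5 were recovered at 2-fold, as were the 50 given 3 and the 50 given -3. Among the measured unchanged genes of the 19775, 0 were called. The simulated arrays were copies of the control with small added noise. Only bright genes were changed, and all probe sets of a gene moved together. Recovery was nearly assured under these settings, so the test checks the calculation and not how often single arrays give false 2-fold calls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.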

Results

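Gene expression was measured in 3 stable PANC-1 lines, one with the empty vector, one expressing wild-type JMJD3 and one expressing a mutant JMJD3. JMJD3 is the protein of KDM6B, a demethylase of trimethylated lysine 27 on histone H3. Each line was represented by 1 array of 54613 probe sets, and there were no replicates. The arrays had median log2 signals of 5.50 for control, 5.48 for wild-type JMJD3 and 5.49 for mutant JMJD3. Of 19775 genes, 12438 were over the floor in control, 12571 in wild-type JMJD3 and 12513 in mutant JMJD3. The series title names HKDC1 and the spectrin cytoskeleton, and the arrays address which genes differ with wild-type JMJD3 and which of those also differ with the mutant.

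HKDC1, a member of the hexokinase family, was bright in the wild-type JMJD3 array and at the floor in the others. Its brightest probe set, 227614_at, read log2 8.02 with wild-type JMJD3, 4.19 in control and 4.24 with mutant JMJD3, which is at least 5.82-fold higher than in either. Probe set 237323_at went the same way (6.07 with wild-type JMJD3, 4.58 in control and 4.73 with the mutant). The other 2 lay within 0.03 of the floor or under it in every array. With the median over its probe sets in place of the brightest, the bound for HKDC1 was a log2 difference of 0.59, under 2-fold. Of the other hexokinases, HK1 was 1.45-fold higher with wild-type JMJD3 than in control and 1.40-fold higher than with mutant JMJD3, and HK2 differed by 0.00 from control.

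KDM6B itself was read by 5 probe sets that did not move together. Probe set 1556067_a_at was 2.30-fold higher with wild-type JMJD3 than in control and 1.89-fold higher with mutant JMJD3, and 1556066_at was 1.66-fold and 1.40-fold higher. The brightest probe set, 41387_r_at, read 7.60 in control, 7.66 with wild-type JMJD3 and 7.65 with mutant JMJD3, and 41386_i_at read 6.99, 6.99 and 6.88. The remaining probe set lay at 5.12 in all arrays. Where these probe sets lie against the introduced coding sequence is not stated, so those that stayed level check neither label.

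At their brightest probe sets the 4 measured spectrin genes were lowest in the mutant JMJD3 array. Each also had a measured probe set that was not lower there than in control, such as 226765_at of SPTBN1 (7.38 in all arrays). SPTAN1, the non-erythroid alpha chain, read 9.32 in control, 9.74 with wild-type JMJD3 and 8.59 with mutant JMJD3, so that wild-type exceeded mutant 2.22-fold and exceeded control 1.34-fold. Its probe set 208611_s_at went the same way, with wild-type over mutant at 1.88-fold, while 214925_s_at and 241150_at read the same in both JMJD3 arrays, and the median over its probe sets was 0.46 on the log2 scale. SPTBN1, the main non-erythroid beta chain, was 1.16-fold lower than control with wild-type JMJD3 and 1.31-fold lower with mutant JMJD3, and SPTB read 6.12, 6.19 and 5.89 in control, wild-type and mutant. Over 4 measured spectrin genes the median log2 difference was 0.10 for wild-type against control, at percentile 65.5 of matched random lists, and -0.31 for mutant against control, at percentile 1.19. Without shared probe sets, which leaves 3 members, the latter median was -0.73 and that of wild-type against mutant went from 0.25 to 0.88. Other settings made them smaller, to -0.19 with the median over a gene's probe sets and to 0.13 with the floor at the 60th percentile. ADD3, an adducin that caps actin and binds it to spectrin, stood out among 17 measured membrane skeleton genes. It was 4.29-fold higher with mutant JMJD3 than in control and 1.45-fold lower with wild-type JMJD3, in the same direction in all 4 of its probe sets.

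**Figure D1:**
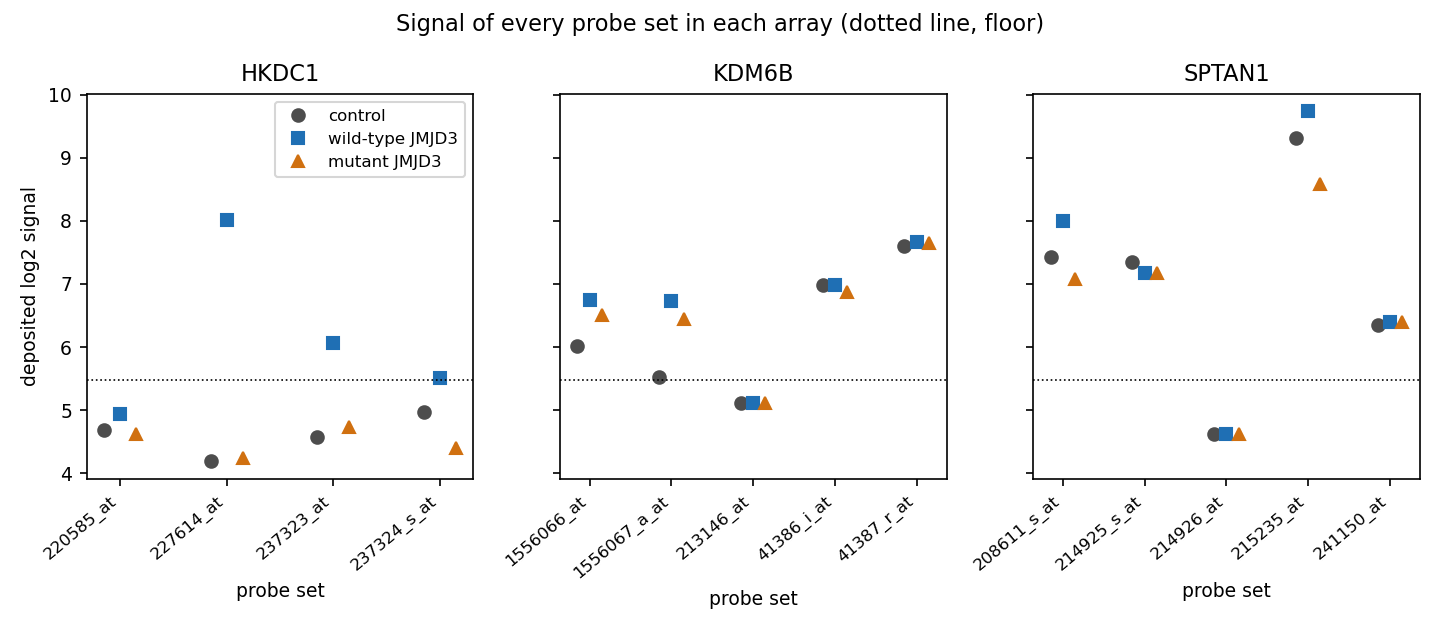
Deposited log2 signal (y axis) of every probe set (x axis) of HKDC1, KDM6B and SPTAN1 in the control, wild-type JMJD3 and mutant JMJD3 arrays, 1 array each, with the floor at 5.48 dotted. For HKDC1 probe set 227614_at the wild-type value is 8.02 against 4.19 and 4.24, while the 5 KDM6B probe sets disagree.

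The first comparison asks which genes differ between wild-type JMJD3 and the empty vector. Of 12697 measured genes, 121 were higher and 166 lower by 2-fold or more with wild-type JMJD3. AGR2, a protein disulfide isomerase of mucus-secreting epithelia, was 10.6-fold higher, the ductal keratin KRT19 5.46-fold, the serine protease inhibitor SPINT2 4.89-fold, and the small GTPase RAB31 4.38-fold. DKK1, a secreted Wnt antagonist, was 4.32-fold higher, and BMP2, a bone morphogenetic protein, 3.76-fold. HBB, the beta globin gene, was 9.06-fold higher, in 3 probe sets of shared sequence and not in the remaining one, which differed by 0.10 on the log2 scale. On the lower side were PMCH, a neuropeptide precursor, at 3.78-fold, the adaptor GRB14 at 3.71-fold, the transporter ABCA5 at 3.27-fold, the glycosyltransferase B3GNT5 at 3.05-fold and the NF-kB subunit REL at 2.77-fold. DACH1, a transcriptional repressor, was at least 5.35-fold lower.

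Among the lists, TGF-beta and SMAD target genes were higher with wild-type JMJD3, with 15 of 20 measured members above control and 4 by 2-fold or more. These were the inhibitors of DNA binding ID2 (3.51-fold), ID3 (2.75-fold) and ID1 (2.53-fold), and the matricellular protein gene CCN2 (2.08-fold). The list median was 0.38, at percentile 99.955 of matched random lists, but 0.07 over the 14 members left without shared probe sets. Genes of actin and its regulators had a median of 0.29 at percentile 99.2, with 19 of 23 members above control, led by gelsolin (GSN, 2.10-fold) and the myosin light chain MYL9 (1.96-fold). HOX genes had 18 of 20 measured members above control and a median of 0.34 at percentile 99.7, though none reached 2-fold. The highest of them was HOXC13 at 1.97-fold. The mutant array had them higher too, 16 of 20 with a median of 0.225 at percentile 97.9. There 2 passed 2-fold, HOXB8 (2.87-fold) and HOXB6. Both were under 2-fold with the floor at the 60th percentile (0.95 and 0.75 on the log2 scale) and with an offset in its place (0.98 and 0.73). The HOX median for wild-type against mutant was 0.00. HOXB8 was 2.07-fold lower with wild-type than with mutant, but under 2-fold with quantile normalization (-0.95). Mesenchymal genes had a median of 0.38 with 16 of 20 above control, including TGFBI (2.87-fold) and the collagen COL5A1 (2.19-fold), while TWIST1, a regulator of mesenchymal state, was 2.03-fold lower. The median of 20 glycolysis genes was 0.15 at percentile 77.4 (0.05 at the lowest under the alternatives), and none of them differed by 2-fold. Of the 33 genes of S and G2/M phase none differed by 2-fold, and their median (0.02) and mean (-0.10) had opposite signs. KIF11 (1.92-fold), CENPF (1.85-fold) and the proliferation marker MKI67 (1.74-fold) were the lowest of them.

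These counts depend on how dim signals are treated. With an offset in place of the floor, 70 genes were higher and 71 lower, and without shared probe sets 79 were higher. For the 121 higher genes, 49 had another measured probe set, and 91.5% of those 82 probe sets were higher as well, 23.2% of them by 2-fold. With the median over a gene's probe sets, GSN differed by 0.70 and COL5A1 by 0.78 on the log2 scale, both under 2-fold. CCN2 (0.99) and TWIST1 (-0.98) fell under 2-fold with quantile normalization, and TWIST1 (-0.82) with the offset too.

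With mutant JMJD3 the 2-fold differences from control were mostly upward. Of 12707 measured genes, 379 were higher and 68 lower by 2-fold or more, so 84.8% of these were higher, while the median over all measured genes was 0.00. AGR2 was 19.2-fold higher, the gap junction protein gene GJA1 15.4-fold, the transport protein gene MAL2 at least 15.2-fold, and the 5-lipoxygenase gene ALOX5 at least 8.34-fold. The aldo-keto reductases AKR1C1 (7.26-fold) and AKR1C2 (5.39-fold) were higher (1.30 and 1.06 on the log2 scale in their other measured probe sets), as were the defensin DEFB1 (6.63-fold), the sterol exporter ABCG1 (at least 6.63-fold), SOX9, a ductal progenitor transcription factor (6.02-fold), fibronectin (FN1, 5.54-fold) and IFITM1, an interferon-induced membrane protein gene (5.46-fold). The drug efflux pump ABCB1 was 3.27-fold lower, TMEM45A 3.20-fold, the aldolase ALDOC 3.05-fold, AIFM2, which encodes the ferroptosis suppressor FSP1, 3.03-fold, the laminin chain LAMA1 2.95-fold, the somatostatin receptor SSTR1 2.85-fold and the LIM protein AJUBA 2.81-fold.

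Glucose uptake and glycolysis genes were lower with mutant JMJD3 in 17 of 20 measured members, with a median of -0.42 that lay below every one of the 10000 random lists. ALDOC was followed by the bifunctional enzyme PFKFB4 (2.68-fold lower) and the glucose transporters SLC2A3 (2.43-fold) and SLC2A1 (2.17-fold). Cholesterol synthesis genes were lower in all 14 measured members, with a median of -0.60, again below all 10000 random lists. HMGCS1 (2.39-fold), SQLE (2.17-fold) and MSMO1 (2.11-fold) passed 2-fold. Hypoxia targets, which share PFKFB4 and SLC2A1 with the glycolysis list, had a median of -0.29 at percentile 0.010, with 12 of 18 lower, and -0.13 without shared probe sets. NF-kB targets and inflammatory mediators were higher, 7 of 21 by 2-fold or more. The chemokine CXCL1 was at least 3.73-fold higher, CCL2 at least 3.23-fold, CXCL8 at least 2.95-fold and CXCL2 2.48-fold. The median of that list was 0.83, above all 10000 random lists, and was 0.51 with the floor at the 60th percentile. In 6 of the 21 members control was at the floor and mutant over it, and over the other 15 the median was 0.30. With wild-type JMJD3 the list was higher as well, in 16 of 17 measured members, with a median of 0.30 at percentile 99.05. Immediate early genes had a median of 0.49 (0.20 without shared probe sets), with 16 of 20 above control, and the transcription factor gene JUN was 4.82-fold higher. With wild-type JMJD3 their median was 0.315 at percentile 99.3, with 13 of 20 above control, and 0.12 at the lowest under the alternatives. Pancreatic and endodermal regulators had 9 of 11 measured members above control and a median of 0.38 at percentile 99.5, which was 0.13 with the floor at the 40th percentile. SOX9, ISL1 (2.03-fold) and FOXA2 (1.62-fold) were the highest, and ISL1 was under 2-fold with quantile normalization (0.96 on the log2 scale) and with the offset (0.83). Of the mesenchymal genes 15 of 21 were above control, with a median of 0.36, and LOX, which crosslinks collagen, was 2.28-fold lower. In the epithelial list MAL2 and KRT19 (4.53-fold) were higher and KRT8 was 2.13-fold lower, around a median of 0.03 at percentile 71.7 that turned sign under some settings.

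With an offset in place of the floor the mutant comparison gave 202 higher and 41 lower genes. Of 235 other measured probe sets of the higher genes, 75.3% went the same way. AIFM2 rests on a shared probe set and differed by -0.17 on the log2 scale without it, and ABCB1 by -0.88 with the median over its probe sets. SLC2A1 (-0.92) and CXCL2 (0.93) fell under 2-fold with the offset, and CXCL8 (0.87) with the floor at the 60th percentile.

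**Figure D2:**
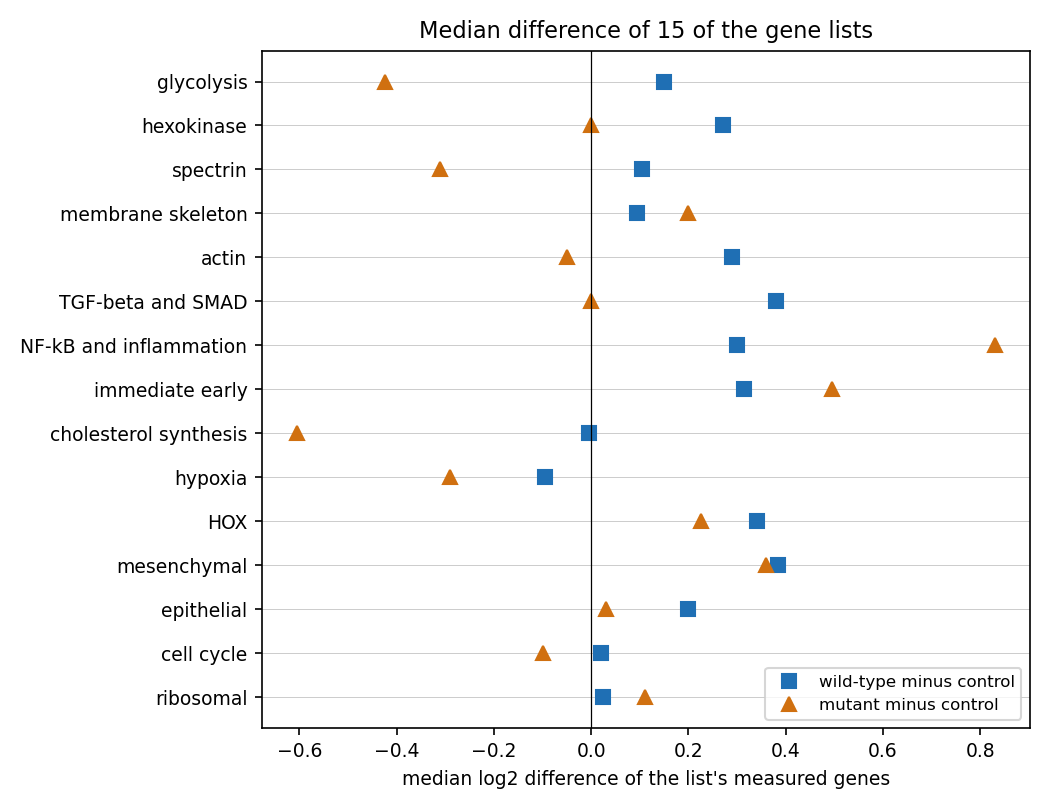
Median log2 difference from control (x axis) of the measured genes of 15 of the lists (y axis), for the wild-type JMJD3 array (squares) and the mutant JMJD3 array (triangles), 1 array each. Glycolysis is at 0.15 with wild-type and -0.42 with mutant, cholesterol synthesis near 0 and at -0.60, and NF-kB targets at 0.30 over 17 measured genes and 0.83 over 21 (0.51 over the same 17).

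Setting the JMJD3 arrays directly against each other gave the most differences. Of 12829 measured genes, 335 were higher and 795 lower by 2-fold or more with wild-type than with mutant JMJD3. Higher with wild-type were HBB (11.2-fold), TNNC1, the slow skeletal and cardiac troponin C gene (at least 6.77-fold), HKDC1, LAMA1 (5.66-fold), the placental alkaline phosphatase ALPP (4.47-fold), the small heat shock protein gene CRYAB (4.14-fold), AJUBA (4.06-fold), the phospholipase PLA1A (4.06-fold), SSTR1 (3.84-fold) and the keratins KRT80 (3.73-fold) and KRT7 (3.12-fold). Lower were the selenium carrier SELENOP (at least 10.3-fold), GJA1 (10.2-fold), KCTD12 (8.17-fold), MAL2 (7.06-fold), TXNIP, an inhibitor of thioredoxin and of glucose uptake (6.45-fold), its arrestin relative ARRDC4 (6.41-fold), the histone genes H2BC4 (8.0-fold) and H2BC21 (6.36-fold), ADD3 (6.23-fold), the sterol exporters ABCA1 (at least 6.02-fold) and ABCG1 (5.62-fold), and complement C5 (at least 5.58-fold).

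Glycolysis genes were higher with wild-type than with mutant JMJD3 in 17 of 20 members, 5 by 2-fold or more, and their median of 0.50 lay above all 10000 random lists. SLC2A3 (3.41-fold), SLC2A1 (3.14-fold), ALDOC (2.97-fold) and PFKFB4 (2.23-fold) led. Actin and its regulators had 19 of 23 higher, with a median of 0.37 at percentile 99.8, and MYL9 (2.87-fold) and the non-muscle myosin heavy chain MYH9 (2.14-fold) passed 2-fold. Cholesterol synthesis genes had 12 of 14 higher and a median of 0.48 (SQLE, 2.08-fold), and TGF-beta and SMAD targets 15 of 21 higher with a median of 0.38, which was 0.06 without shared probe sets. ID3 was 2.64-fold higher. NF-kB targets had a median of -0.19 that rested on 4 members over the floor only with mutant, as it was -0.03 over the other 17, with PTGS2, the inducible cyclooxygenase, 3.89-fold and CXCL1 3.07-fold lower with wild-type. In the mesenchymal list FN1 (3.34-fold), TWIST1 (2.97-fold) and ZEB1 (2.23-fold) were lower with wild-type, around a median of 0.02 that turned sign under some settings. With an offset in place of the floor the counts were 208 higher and 479 lower. Without shared probe sets, the log2 differences of HBB (0.60), KRT7 (0.52) and MYL9 (0.38) fell below 2-fold. So did SQLE (0.76), ZEB1 (-0.82) and MYL9 (0.95) with the median over their probe sets, and PFKFB4 (0.96), SQLE (0.99) and, by less than the rounding, MYH9 with the offset.

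The wild-type JMJD3 array was higher than both others by 2-fold or more for 32 genes and lower than both for 109. HBB, HKDC1, BMP2, CRYAB, TNNC1, ELAPOR1, ID3 and PLA1A had the largest margins on the higher side. ELAPOR1 was 2.68-fold over control and 3.05-fold over mutant. Those with the largest margins on the lower side were SELENOP, C5, DACH1, B3GNT5, GRB14, ABCA5, REL and the small GTPase ARL6. SELENOP was at least 4.08-fold under control and C5 at least 3.51-fold. ARL6 against control (-0.77) and DACH1 against mutant (-0.96) were under 2-fold with the floor at the 60th percentile, and ARL6 (-0.95) with the offset too. The mutant array was higher than both others for 223 genes and lower for 43, while control was higher for 5 and lower for 53. When each gene's 3 values were shuffled among the arrays, each array was higher than both others for 86.5 to 86.9 genes and lower for 68.0 to 68.7 on average. Shuffling keeps the total over the 3 arrays, so these averages are even shares of it. An excess in one array therefore forces a deficit in the others, and the counts below are not separate results. They show only how unevenly these genes fell among the arrays. The mutant array's 223 lay above the highest shuffle, at 110, and the wild-type array's 109 lower genes above the highest of 91. The wild-type array's 32 higher genes lay below the lowest shuffle, at 64, as did the mutant's 43 lower genes (lowest 50) and the control's 5 higher ones (lowest 61), while the control's 53 lower genes lay within the range of 49 to 96.

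Differences from control were nearly unrelated between the JMJD3 arrays. Across 12867 genes, which are not independent replicates, Pearson's r of the differences was 0.06. Shuffling gave 0.50 on average, with a range of 0.47 to 0.53. It makes the 3 arrays interchangeable, which alone sets r near 0.50. A shared control gives a lower r where it varies less than the other arrays, so the gap alone shows no opposition between them. The covariance was 0.010 against 0.114 after shuffling. By 2-fold or more, 53 genes were higher in both JMJD3 arrays and 5 lower in both. Shuffling gave 68.7 and 86.8 on average, and independent lists of these sizes would share 3.66 and 0.90. Shuffling does not keep the list sizes, and it spreads differences between the JMJD3 arrays over the control. Only 68 genes were lower with mutant JMJD3, so the lower overlap could not have reached 86.8. The shuffled overlaps therefore cannot tell whether more genes were shared than the common control array gives. Both overlaps exceeded those of independent lists, which take no account of that array. Among the shared genes, AGR2, KRT19, RAB31, SPINT2, MAGED1 (4.06-fold with wild-type and 3.76-fold with mutant), the raft protein gene MALL (4.23-fold and 2.71-fold), SOX9 (3.43-fold and 6.02-fold), DKK1 (4.32-fold and 2.11-fold) and ID2 (3.51-fold and 2.99-fold) were higher. PMCH (3.78-fold and 2.69-fold), HMGCS1 (2.0-fold and 2.39-fold) and DPEP2NB (at least 6.11-fold in both) were lower. HMGCS1 with wild-type JMJD3 lay between -0.99 and -0.85 on the log2 scale, under 2-fold, in 4 of the alternatives. Opposite 2-fold differences were seen in 1 gene higher with wild-type and lower with mutant, TNNC1 (3.10-fold higher and at least 2.19-fold lower, a log2 bound of -0.44 with the floor at the 60th percentile), and in 9 genes the other way, SELENOP, ABCA1 and KCTD12 among them. Each of these 3 lost one of its 2-fold differences under some setting, ABCA1 with wild-type JMJD3 (-0.42 with the floor at the 60th percentile), SELENOP with mutant JMJD3 (0.72 with the median over its probe sets) and KCTD12 with wild-type JMJD3 (-0.99 with the offset).

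**Figure D3:**
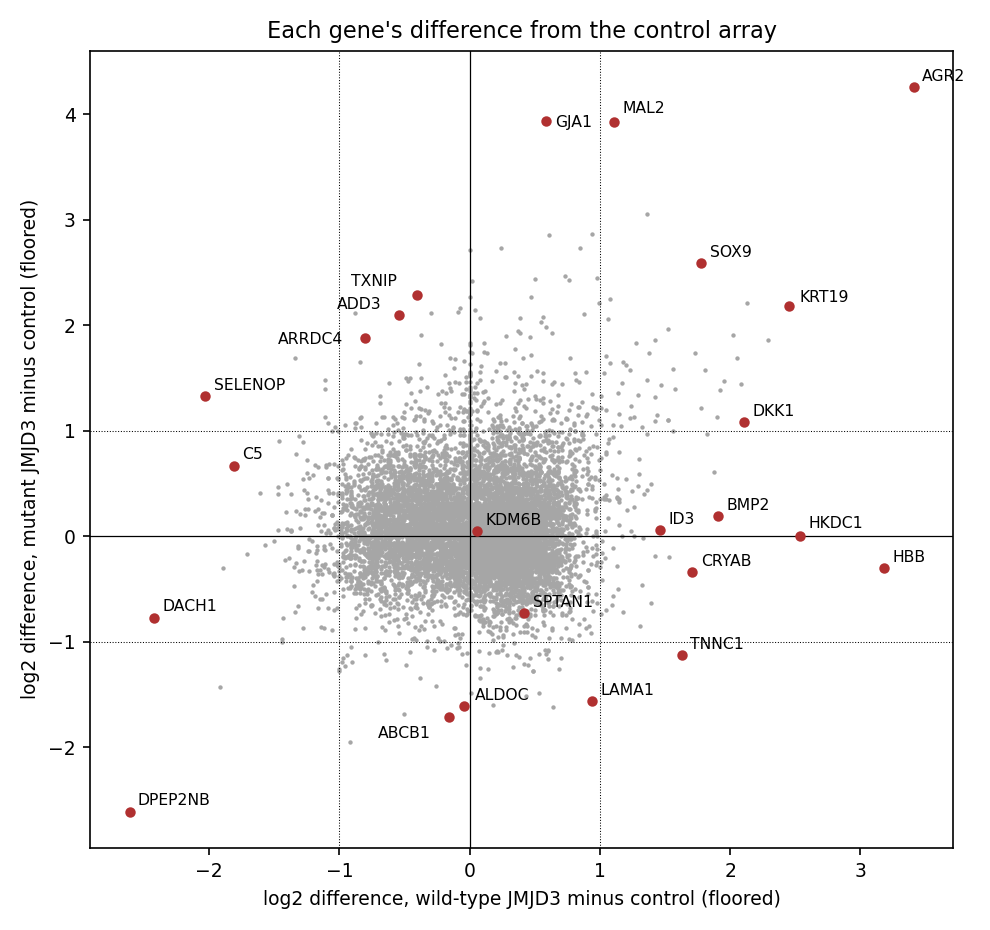
Each of 12867 genes by its floored log2 difference from control in the wild-type JMJD3 array (x axis) and in the mutant JMJD3 array (y axis), 1 array each, with 2-fold differences dotted and named genes in red. AGR2 (3.41 and 4.26) is high in both, HKDC1 and HBB are high in the wild-type array alone, and GJA1 (0.59 and 3.94) and TXNIP (-0.40 and 2.29) in the mutant array alone.

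Markers of other cell types were mostly at the floor. Of 12 leukocyte markers with a probe set 3 were measured, of 6 acinar markers 1 at most, and of 10 endothelial markers 5 at most, and of these 3 lists only ESAM, an endothelial adhesion protein gene, passed 2-fold in any comparison. ESAM was 2.46-fold higher with wild-type than with mutant JMJD3, as was the fibroblast marker PDGFRB (2.35-fold), and the neuronal marker SNAP25 was 2.16-fold higher with mutant JMJD3 than in control. With the offset all 3 were under 2-fold, ESAM at 0.94, PDGFRB at 0.88 and SNAP25 at 0.97 on the log2 scale. Of 12 fibroblast markers 5 were measured for wild-type against control, 4 of them higher, with a median of 0.28 at percentile 92.1, and 6 for wild-type against mutant, with a median of 0.245 at percentile 93.9. Ribosomal protein genes, a reference list, had medians of 0.02 for wild-type and 0.11 for mutant against control. Probe sets without a gene name were on average 0.17 lower in the wild-type array than in control, against 0.003 lower for probe sets of 1 gene, and zinc finger genes named ZNF had a median of -0.10 there, with 1 of 329 higher and 10 lower by 2-fold. For wild-type against mutant JMJD3 the ZNF median was -0.23, with 0 of 341 higher and 40 lower. Whether these shifts are related to the lower genes of the wild-type array was not tested.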

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

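The test of the middle array, the test of unnamed probe sets and the count of HBB probe sets were chosen after the result was seen, and the restriction to bright genes after the correlation over all genes was seen but before its own result. The report's comparisons use only probe sets with 1 gene. Among the unnamed probe sets, 19 were 2-fold or more higher with wild-type JMJD3 than in control and 155 lower, and 117 were higher with mutant JMJD3 and 46 lower. The higher ones are signals above the control level in data that the gene comparisons leave out. Their shares of the measured unnamed probe sets, 0.50% and 3.07%, were close to those of probe sets of 1 gene, 0.71% and 2.95%, but the shares of lower ones, 4.09% and 1.21%, exceeded those of probe sets of 1 gene, 1.77% and 0.66%.

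The differences of the wild-type and mutant JMJD3 arrays from control were less correlated, at 0.06, than in shuffled arrays, where r was at least 0.47. Shuffling makes the arrays interchangeable, which holds r near 0.50 under any scaling or choice of genes. A shared control need not give that value, so the shuffled values below do not show a deficit that needs an explanation. Control was the middle array in 51.2% of the 27943 probe sets with 3 different values, which restates the low correlation, so joint summarisation of the arrays stays open. After quantile normalization r was 0.061 with a lowest shuffled value of 0.474. The columns already had nearly the same distribution, so that step could hardly change r and does not decide on unequal scaling. Among 7397 genes bright in all arrays r was 0.020, with a lowest shuffled value of 0.466, so the low correlation was not confined to dim probe sets. A difference between single RNA preparations or hybridisations stays open, since each group had 1 array and unnamed probe sets shifted by -0.167 more than probe sets of 1 gene between wild-type and control. The JMJD3 form itself, which the design names, is an open and untested explanation, as is a difference between single selected lines.

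Identical values in all 3 arrays were found in 34.8% of the probe sets with a mean under the floor and in 2.08% of those over the 75th percentile. Arrays summarised 1 at a time and rounded to 2 decimals would give about as many differences of 0.01 as exact ties, but between wild-type and control there were 52.2 times as many ties. Median polish of 3 arrays together gave ties in 43.7% of simulated unchanged probe sets of 11 probes, under assumed noise, so a joint summary of this kind is a candidate explanation. It was not shown to be the step used, and no biological explanation was tested. How the deposited values relate to the MAS5 step that the submitters' notes name is therefore uncertain.

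HBB was higher in the wild-type array alone, with log2 signals of 10.71 there, 7.53 in control and 7.23 with mutant JMJD3. Erythroid cells in the sample would bring other red cell transcripts, but 0 of 10 other erythroid markers with a probe set were higher by 2-fold, with HBD at 5.10, HBM at 4.94 and ALAS2 at 5.12 in the wild-type array. SELENBP1, also a gene of other tissues, was the only bright one of them, at 9.49 against 9.21 in control. The rise was not confined to 1 probe set, as 3 of the 4 HBB probe sets were higher, a count made with the values already seen. The remaining one, without shared sequence, differed by 0.10 on the log2 scale. Whether the 3 have probes in common was not checked, so a fault common to them stays open. Those 3 share sequence with other transcripts, so a related transcript and HBB itself both stay open and were not tested.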

How the results depend on the processing

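No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Of 98 recomputed counts 77 stayed within 1.5 times, and r of the differences from control moved by less than 0.1 under each of the 7 alternatives and among bright genes, a restriction chosen after seeing r over all genes. Of 4915 recomputed differences of named genes, 124 fell below 2-fold, 31 rose above it and 1 turned sign (KLF2, mutant against control, -0.02 without shared probe sets). Some of the 4915 were under 2-fold at the outset, so the 124 understate the loss of 2-fold calls. For wild-type against control the offset kept 70 of the 121 higher genes and 70 of the 166 lower ones. For mutant against control it kept 197 of 379 and 41 of 68, and for wild-type against mutant 208 of 335 and 477 of 795. List and family medians stayed within the spread between probe sets of a gene in 707 of 746 cases. That spread, 0.17 to 0.24 on the log2 scale, is as wide as many list medians, so staying within it does not show stability. Some medians turned sign. That of hypoxia targets for wild-type against mutant went from 0.05 to -0.20, and that of membrane skeleton genes for wild-type against control from 0.095 to -0.06.

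With an offset in place of the floor, genes higher and lower were 70 and 71 for wild-type against control, 202 and 41 for mutant against control, and 208 and 479 for wild-type against mutant. The genes higher and lower than in both other arrays were then 20 and 36 for wild-type, 113 and 26 for mutant and 2 and 24 for control. An offset shrinks differences of dim genes by construction. Without shared probe sets 79 genes were higher with wild-type than in control, and control was higher than both for 2 and lower for 29. Scaling to one median also left control higher for 2.

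Without shared probe sets, which leaves fewer members, the spectrin medians were -0.73 for mutant against control and 0.88 for wild-type against mutant, the hexokinase median was 0.54 for wild-type against control (0.54 too with the floor at the 60th percentile), the NF-kB median was 0.56 for mutant against control, and the TGF-beta and SMAD medians were 0.07 for wild-type against control and 0.06 for wild-type against mutant. The NF-kB median was 0.62 with the floor at the 40th percentile and 0.51 with it at the 60th. With the median over a gene's probe sets, HKDC1 was 0.59 over control and over mutant, and SPTAN1 0.46 for wild-type over mutant. The cause was not tested for these.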

Other observations

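Some histone genes were higher in the mutant JMJD3 array. They were picked out after their values were seen, and only H2A, H2B and linker histone genes were counted. Of 7 measured H2A genes 4 were 2-fold or more higher than in control, with a median of 1.11, as were 2 of 9 H2B genes (median 0.64) and 1 of 5 linker histone genes (median 0.40). With wild-type JMJD3 the medians were 0.06, -0.15 and 0.12, and 0 of these genes passed 2-fold. H2AC8 differed from control by 2.07 and H2AC6 by 1.35 on the log2 scale with mutant JMJD3, and H1-2 by 1.23, while H2AC4 differed by 0.22 and H2BC15 by 0.00. Under the alternatives the medians in the mutant array stayed above 0 and ranged from 0.96 to 1.23 for H2A, from 0.12 (without shared probe sets) to 0.87 for H2B and from 0.24 to 0.78 for linker histones. The histone genes resemble each other in sequence, so single members are uncertain, and S and G2/M phase genes had a median of -0.10 in the same comparison.

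Single members of other lists differed from control. The list of the unfolded protein and integrated stress responses had a median of 0.275 at percentile 97.0 with wild-type and 0.155 at percentile 96.3 with mutant, and that of CDK inhibitors and p53 targets 0.135 at percentile 75.5 and 0.10 at percentile 85.5. Asparagine synthetase, ASNS, was 4.63-fold higher with mutant JMJD3 than in control and 1.99-fold higher with wild-type. The p53 target TP53I3 was 2.13-fold lower with mutant JMJD3 and 1.52-fold higher with wild-type. The CDK inhibitor gene CDKN1C was 2.10-fold higher with wild-type and 1.89-fold higher with mutant, but differed by 0.73 on the log2 scale with wild-type in the median over its probe sets. AXIN2, a feedback target of Wnt signalling, was 2.33-fold lower with mutant JMJD3, and differed by -0.81 in the median over its probe sets. Of the genes that write or erase H3K27 methylation none differed from control by 2-fold in either JMJD3 array at its brightest probe set, though a dimmer probe set of KDM6B was 2.30-fold higher with wild-type. KDM6A, the closest relative of KDM6B, was 1.77-fold lower with wild-type JMJD3 in its brightest probe set, but differed by -0.03 on the log2 scale in the other measured one.

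As a hypothesis, the lower cholesterol synthesis genes and the higher exporters ABCA1 and ABCG1 in the mutant array might belong to one sterol response through LXR. The other LXR targets should then be higher too. Without ABCA1 and ABCG1 the 8 measured targets had a median of -0.10 against control, at percentile 8.62 of matched random lists. That lay in the range set in advance as counting against higher LXR targets, so they were not higher as a group. MYLIP (0.99), APOE (0.19) and NR1H3 (0.14) were above control. SREBF1 (-0.67), SCD (-0.36), SMPDL3A (-0.21) and LPCAT3 (-0.20) were below it. As the members went both ways, their median does not settle whether LXR was involved.

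A further hypothesis is that BMP2 and the ID genes in the wild-type array may reflect BMP signalling. Without ID1, ID2 and ID3, the 11 measured BMP targets had a median of 0.27 for wild-type against mutant, at percentile 93.4 of matched random lists, short of the percentile set in advance, so the question stays open. SMAD6 (0.87) and SMAD7 (0.64) were higher and SMAD9 (-1.99) lower with wild-type.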
